A study of Danio rerio with 332 samples.

How the data were processed

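Single-cell RNA was measured in 332 zebrafish cells carrying a mitfa-driven green fluorescent reporter. Per the labels' protocols, each GEO sample was 1 living fluorescent cell sorted from a melanoma or from the tissue left after its regression, and its polyadenylated RNA was amplified with the Smart-seq2 full-length method and made into a Nextera XT library. Per the submitters' processing notes, FastQC 0.11.4, cutadapt, STAR and Salmon were used with the GRCz11 genome build. The role of each tool, the other versions, the annotation release and any filtering of cells were not given in the sources used here.

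Per the file headers, the authors deposited for each cell an estimated count and a TPM (relative abundance corrected for transcript length and library total) for every feature, in the layout that Salmon writes. Every file held the same 53316 features, of which 53224 were zebrafish transcripts and 92 were spike-in control sequences. The labels did not mention the spike-ins, and the amount added was not given in the sources used here. Of the estimated counts above 0, 58.7% were whole within 0.001, and all were rounded to whole numbers before use. The deposited TPM values were used only as an alternative.

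The files identified transcripts, not genes, and did not pair them with gene names. Of these transcript IDs, 0 matched the reference tables used here, so no gene could be named. The 29 gene lists fixed before the data were examined, the cell type markers and the level of mitfa itself could therefore not be computed, and the 12 planned list results were not obtained. No clusters of cells are reported, and cells of other types were not removed. Transcripts of 1 gene share reads that Salmon divides by estimation, so the level of a single transcript is uncertain. Levels could not be summed to genes.

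Groups were taken from the labels. The cell filter, the rule for the thinning depth, the rule for named items and the comparisons were fixed before the data were examined. Cells with at least 50000 reads in zebrafish transcripts and at least 1000 transcripts were kept, which left out 1 cell. Each of the 331 remaining cells was thinned without replacement to 50000 reads, the depth given by the fixed rule. Thinned reads were summed per group, scaled to the group total as CPM and compared as log2 ratios with a pseudocount of 1 CPM. Doublets were not called, because each well was sorted as 1 cell; libraries with many transcripts were examined instead.

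No label named an animal, so each group counted as 1 sample and no test, p-value or count of changed transcripts was computed from cells. Intervals are exact 95% Poisson intervals for sums, exact binomial intervals for shares of cells, and exact conditional binomial intervals for ratios of sums. They cover counting error only, because amplified reads without molecular identifiers are not independent molecules. A level of 0 was set to 3 counts over the group where a fold was given.

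The cells fell into 3 library pools, crossed with the groups, and 2 sets of i7 indexes. Primary superficial cells were all in index set 2 and regressed superficial cells all in index set 1. Within an index set, the groups also lay largely on different i5 indexes. An index pair held the same group in every pool that used it. Group and i5 index can therefore hardly be told apart in the comparisons, and holding out a pool does not separate them. Values were repeated within pools and, where both groups had cells, within index sets. The SD over pools describes technical and sampling spread, since cells of 1 animal can be in several pools.

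Transcripts were named by a fixed rule. They needed at least 50 CPM in the higher group, reads in at least 40% of its cells, no cell with more than 20% of its reads, and a log2 ratio of at least 1 in size in the thinned sums, in the mean of per-cell CPM and in every pool with at least 5 cells of both groups. Of these, the largest 2 in each direction are printed per comparison. The rule had asked for 10 genes per direction with symbols, which could not be applied.

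The gene lists were replaced, after the transcript IDs were seen, by sets of transcripts chosen from the data. For each pool in turn, the 100 transcripts with the largest ratio in each direction were chosen in the other pools with the same limits on level, cells and single-cell share. Their median log2 ratio was then measured in the pool left out, and the mean ± SD over the 3 pools is given. Its percentile among 10000 random lists of 100 transcripts, drawn from the transcripts that met those limits and matched in 10 bins of mean expression, is given as a description. Selection and measurement thus used different libraries. For 10 libraries that resembled their same-index partners in other pools, the RNA chosen on and measured may have been the same, so the sets were repeated without them. Comparisons that share a group are expected to agree in part. The sets of regressed and of recurring against primary nodular cells were therefore measured in every other group against those cells, which was added after the data were seen.

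Neighbours were found from log-transformed CPM-scaled thinned counts of the 2000 most variable transcripts, with 20 principal components. For each cell the 10 nearest cells in the other pools were counted by group and set beside the share those groups had among the cells of those pools. This measure was also added after the data were seen.

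The held-out sets were tested on simulated data, in which the 80 primary nodular cells were split at random into 2 groups. In one group 100 transcripts were lowered 4-fold, and in the other group another 100. These were drawn only from transcripts above limits on level and share of cells that were set higher than those for the sets. Recovery of transcripts nearer to the limits of the sets was therefore not tested. The sets chosen as higher gave a held-out median of 1.76 ± 0.07 (SD, 3 pools) and those chosen as lower −1.78 ± 0.05, where the planted transcripts themselves had median log2 ratios of 2.00 and −1.93. With nothing changed they gave 0.03 ± 0.20 and 0.11 ± 0.18. Primary nodular cells alone were split at random here, whereas the compared groups lay largely on different i5 indexes within an index set. The compared groups may also come from different animals. The values with nothing changed therefore cannot show what held-out median i5 index or animal alone would give. The neighbour measure was not tested on simulated data.

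Alternatives covered unthinned sums, means of per-cell CPM or TPM, a pseudocount of 10 CPM, median-of-ratios scaling, a limit of 200 CPM, other cell filters, another random draw, a depth of 20000 reads, each index set, set means, and leaving out libraries that stood apart. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.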

Results

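Single-cell transcriptomes of zebrafish melanoma were compared across 5 groups. The fish carried a BRAF oncogene driven by the promoter of mitfa (the master transcription factor of the melanocyte lineage), the vc7 mutant allele of mitfa and a p53 mutation. Cells with the mitfa-driven green reporter came from primary nodular tumours (80 cells), primary superficial tumours (43), regressed nodular (61) and regressed superficial sites (63), and nodular tumours at the beginning of recurrence (85). The regressed sites represent residual disease. Of the recurring nodular cells, 84 passed the filter, and every cell of the other groups passed.

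Reads assigned to zebrafish transcripts ranged from 45211 to 1476760 per deposited cell. The median was 263128 in primary nodular, 508796 in regressed nodular, 290201 in recurring nodular, 618838 in primary superficial and 534853 in regressed superficial cells. All values were therefore taken from cells thinned to 50000 reads, unless another depth is named. No label named an animal, each group counted as 1 sample, and no difference between groups has a replicate check. The files identified transcripts only and did not pair them with gene names, so transcripts are given by their IDs.

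Regressed nodular cells held fewer transcripts than primary nodular cells at the median. Their median at 50000 reads was 1830, against 2619 in primary nodular and 2163 in recurring nodular cells, and it was below that of primary nodular cells in each pool (1830 against 3266, 2119 against 2748 and 1773 against 2209). Recurring nodular cells lay below regressed ones in pool 2, at 2045. Unthinned, the medians over all pools were 2504, 3038 and 2730. In index set 2 the order was not kept, with 2221 in regressed, 2093 in primary and 1862 in recurring nodular cells, whereas index set 1 gave 1646, 2748 and 2582. Superficial cells had medians of 3363 in primary and 3282 in regressed cells (4556 and 4256 unthinned). In pool 1 primary superficial cells, at 2657, lay below primary and recurring nodular cells (3266 and 3031).

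Spike-in control RNA took 3.44% of the reads at the median of regressed nodular cells, 1.94% in primary nodular, 2.12% in recurring nodular, 0.864% in primary superficial and 1.64% in regressed superficial cells. Regressed nodular cells lay above primary nodular cells in every pool (4.05% against 1.40%, 3.44% against 2.59% and 2.99% against 1.95%) and in both index sets (4.17% against 2.06% and 2.14% against 1.73%). Regressed superficial cells lay above primary superficial cells in 2 of the 3 pools and below them in pool 1, where only 5 primary superficial cells were measured.

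**Figure D1:**
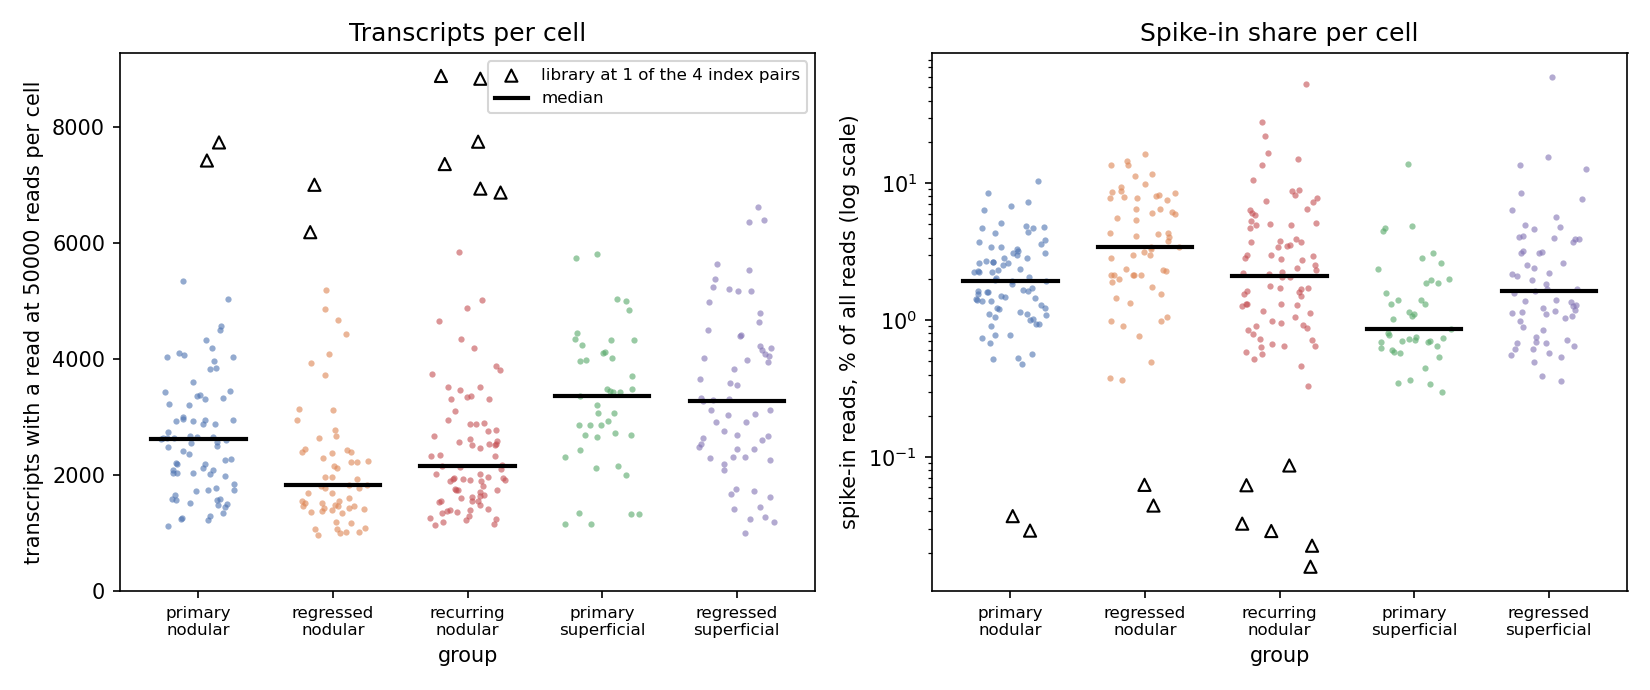
Each point is 1 cell of the group named on the horizontal axis, with the number of transcripts that had a read at 50000 reads (left) and the percent of reads from spike-in RNA on a log scale (right); bars mark group medians and triangles the 10 libraries at 4 index pairs described in the text. Regressed nodular cells have a median of 1830 transcripts and 3.44% spike-in reads, and the triangles lie at 6181 transcripts or more.

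A small number of libraries stood apart. At 4 index pairs, 10 libraries held 6181 to 8871 transcripts (median of the others, 2513) and a median of 0.0348% spike-in reads (others, 2.05%); 2 were labelled primary nodular, 6 recurring nodular and 2 regressed nodular. In pool 2, 10 further libraries formed 5 pairs with the same i5 index and correlations of 0.708 to 0.899 across transcripts; 2 were primary nodular, 2 recurring nodular, 2 regressed nodular and 4 regressed superficial. Transcripts are not independent replicates. All other libraries with the same index pair in different pools were treated as different cells. Same-index libraries in different pools had a median correlation of 0.540, against 0.529 for those of the same group with other index pairs. Their counts differed by a median chi-square of 29.4 per degree of freedom, where 1 is sampling noise of reads. Both medians for same-index libraries include those with many transcripts, and a chi-square above 1 alone does not show different cells.

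The first comparison asked how nodular and superficial primary tumours differed. Transcripts chosen as higher in nodular cells in other pools had a median log2 ratio of 1.67 ± 0.58 (SD, 3 pools) in the pool left out, and those chosen as lower −1.57 ± 0.60. Random lists had medians of 0.25 and −0.23, and the sets lay at percentiles 100 and 0. The transcript ENSDART00000074290 reached 525 CPM (95% interval 502 to 547) in primary nodular cells and 7.44 CPM (4.25 to 12.1) in primary superficial cells, a ratio of 70.5 (43.3 to 124). It was detected in 53.8% of the nodular (42.2 to 65%) and 6.98% of the superficial cells (1.46 to 19.1%). Its log2 ratio varied widely over the 3 pools, at 9.31, 4.34 and 8.33. ENSDART00000171722 had 126 CPM (115 to 137) in nodular cells and 1 read in superficial cells, a ratio of 270 (48.2 to 10678). In the other direction, ENSDART00000003042 had 374 CPM (349 to 401) in superficial cells and 3 reads in nodular cells (log2 ratio −7.75), and ENSDART00000152821 had 122 CPM (108 to 138) against 2.25 (1.03 to 4.27). Of the reads of ENSDART00000003042 in superficial cells, 18.4% came from 1 cell. The higher set was 1.06 within index set 2, the index set that holds all primary superficial cells. Nodular and superficial primary cells also differed in median transcripts (2619 and 3363) and spike-in share (1.94% and 0.864%); in pool 1 the spike-in shares lay the other way (1.40% and 1.86%). The log2 ratio of ENSDART00000171722 was 6.43, and 7.28 unthinned.

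Residual disease was next compared with the primary tumour in nodular melanoma. Transcripts chosen as higher in regressed cells had a held-out median of 0.94 ± 0.14 (random lists −0.04, percentile 100), and those chosen as lower one of −1.70 ± 0.27 (random lists −0.57, percentile 0). ENSDART00000009689 was at 872 CPM (840 to 906) in regressed and 56.8 CPM (49.6 to 64.6) in primary cells, a ratio of 15.4 (13.4 to 17.7). Of its reads in regressed cells, 18.8% came from 1 cell, which the interval does not cover. Its log2 ratio was 3.62, 3.95 and 4.03 in the 3 pools. A read was found in 62.3% of regressed (49 to 74.4%) and 80% of primary cells (69.6 to 88.1%), and 77% and 88.8% unthinned, so the shares lay in the opposite order to the levels and no order was read from them. ENSDART00000053153 was at 571 CPM (545 to 599) against 55 (48 to 62.8), a ratio of 10.4 (9.03 to 12). Its shares of cells with a read, 73.8% and 77.5% (78.7% and 93.8% unthinned), also lay in the opposite order to the levels.

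Among transcripts lower in regressed nodular cells, ENSDART00000164170 was at 29.5 CPM (23.7 to 36.3) against 836 (807 to 864) in primary cells, with reads in 11.5% (4.74 to 22.2%) and 45% (33.8 to 56.5%) of the cells. The 3 pools gave log2 ratios of −6.75, −4.10 and −7.98 for it. ENSDART00000156574 had 2 reads in regressed cells and 89.0 CPM (80 to 98.7) in primary cells, a log2 ratio of −5.76. The fewer transcripts and higher spike-in share of regressed nodular cells accompanied these sets. Random lists drawn for the lower set were themselves at −0.57, whereas those for the higher set were at −0.04. Transcripts of the former had to meet the limits on level and cells in primary cells, so part of their low value can come from that choice. Without the 20 libraries that stood apart, the higher set was 0.86 and the log2 ratio of ENSDART00000164170 was −6.03 instead of −4.78. With deposited TPM that of ENSDART00000156574 was −4.48. Within index set 1 the sets were 1.11 and −2.05, and within index set 2 the lower set was −1.05; there too few transcripts met the limits for a higher set.

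The same question in superficial melanoma gave sets of 1.82 ± 0.46 (random lists 0.14, percentile 100) and −1.47 ± 0.35 (random lists −0.37, percentile 0). ENSDART00000164915 was at 1385 CPM (1344 to 1427) in regressed and 7.91 CPM (4.61 to 12.7) in primary superficial cells, a ratio of 175 (109 to 301). The 3 pools gave log2 ratios of 10.6, 6.89 and 7.77 for it. ENSDART00000185211 was at 172 CPM (158 to 187) in regressed cells and had 0 reads in primary superficial cells, which is at least 123-fold higher against 3 counts over the group. Of its reads in regressed cells, 18.5% came from 1 cell. With deposited TPM and a pseudocount of 1 TPM its log2 ratio was 5.22. ENSDART00000111199 was at 1.59 CPM (0.515 to 3.70) in regressed and 341 CPM (317 to 367) in primary cells, a log2 ratio of −7.05 that was −7.80 unthinned. ENSDART00000140957 had 0 reads in regressed cells and 100 CPM (87.1 to 114) in primary cells, at least 105-fold lower. Unthinned, 3.17% of the regressed superficial cells had a read of it. Median spike-in shares were 1.64% in regressed and 0.864% in primary cells. No index set held both groups, so index set and group cannot be told apart in this comparison.

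The transcripts named in either subtype were also read in the other. ENSDART00000009689 had a log2 ratio of 6.99 in superficial cells, at 4963 CPM in regressed and 38.1 CPM in primary cells, and ENSDART00000053153 one of 4.26. ENSDART00000164170 had −5.30 in superficial cells, and ENSDART00000111199 and ENSDART00000140957 had −6.67 and −5.43 in nodular cells. Agreement was poor for the others. ENSDART00000164915 had 0.18 in nodular cells, with pools at −6.34, 0.82 and 5.14, and ENSDART00000185211 had 1.105, with pools at 2.84, 0.25 and 0.98. ENSDART00000156574 had −1.01 in superficial cells, with pool 3 at 0.48. As sets, transcripts chosen as higher in regressed nodular cells had a held-out median of 0.28 ± 0.13 in superficial regression (random lists −0.10, percentile 100). Those chosen as lower had −0.30 ± 0.34 (random lists −0.17, percentile 10), which did not exceed its spread over pools. Transcripts chosen in superficial regression had 0.13 ± 0.10 (random lists −0.27, percentile 100) and −0.71 ± 0.23 (random lists −0.41, percentile 0.08) in nodular regression. The difference between the subtypes was not tested. The higher nodular set ranged from 0.04 with deposited TPM to 0.54 as a mean, and the higher superficial set from 0.035 with deposited TPM to 0.31 with median-of-ratios scaling.

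**Figure D2:**
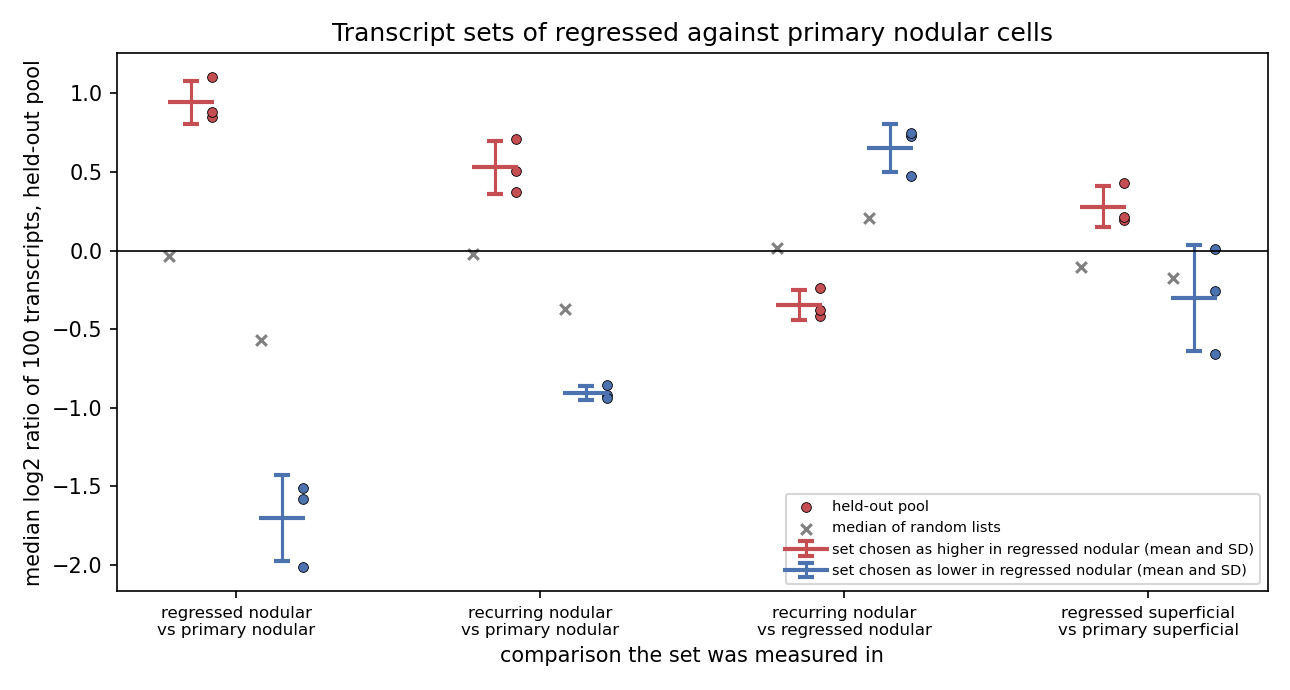
Median log2 ratio of 100 transcripts chosen as higher (red) or lower (blue) in regressed than in primary nodular cells, measured in the pool not used to choose them, for the comparisons on the horizontal axis; points are the 3 pools, bars their mean and SD, and crosses the median of random lists. The sets lie at 0.94 and −1.70 in regressed against primary nodular cells and at 0.53 and −0.90 in recurring against primary nodular cells, where a group that took no part in the choice would also lie nearer to 0.

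Recurring nodular cells were compared with regressed cells to ask what differed at the beginning of recurrence. Transcripts chosen as higher had a held-out median of 1.15 ± 0.23 (random lists 0.26, percentile 100), and those chosen as lower −0.42 ± 0.29 (random lists 0.01, percentile 0). ENSDART00000141338 was at 141 CPM (130 to 153) in recurring and 11.5 CPM (7.99 to 16) in regressed cells, a ratio of 12.3 (8.76 to 17.9). ENSDART00000024207 was at 173 CPM (161 to 186) against 18.4 (13.9 to 23.8), with reads in 56% (44.7 to 66.8%) and 9.84% (3.70 to 20.2%) of the cells. ENSDART00000049900 was at 39.5 CPM (33.7 to 46) against 576 (549 to 604), and ENSDART00000167121 at 18.3 CPM (14.5 to 22.9) against 217 (201 to 235). Recurring and regressed nodular cells also differed in median transcripts (2163 and 1830) and spike-in share (2.12% and 3.44%), although in index set 2 the order of both turned, with 1862 and 2221 transcripts and 2.26% and 2.14% spike-in reads. Unthinned, the log2 ratio of ENSDART00000141338 was 2.61 instead of 3.51 (pools 7.47, 3.70 and 2.60), that of ENSDART00000024207 3.76 instead of 3.17, and that of ENSDART00000167121 −2.63 instead of −3.50.

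Against primary nodular cells, the sets of recurring cells were 1.04 ± 0.25 (random lists 0.03, percentile 100) and −1.29 ± 0.03 (random lists −0.37, percentile 0). ENSDART00000009689, also named in residual disease, was at 3495 CPM (3438 to 3552) in recurring cells, a ratio to primary nodular cells of 61.6 (54 to 70.5), with reads in 98.8% of the cells (93.5 to 99.97%). ENSDART00000127604 was at 349 CPM (331 to 367) against 12.3 (9.06 to 16.2), with reads in 60.7% (49.5 to 71.2%) and 6.25% (2.06 to 14%) of the cells. ENSDART00000016090 was at 31 CPM (25.9 to 36.8) against 440 (419 to 461), and ENSDART00000145821 at 13.3 CPM (10.1 to 17.3) against 125 (114 to 136), a log2 ratio of −3.14 that was −2.05 unthinned. Within index sets 1 and 2 the higher set was 1.41 and 0.65, and the lower set −2.25 and −0.85.

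The sets of regressed cells were also measured in recurring cells. Transcripts chosen as higher in regressed nodular cells had a median of 0.53 ± 0.17 in recurring against primary cells (random lists −0.02, percentile 100) and −0.35 ± 0.09 in recurring against regressed cells (random lists 0.02, percentile 0). Those chosen as lower had −0.90 ± 0.05 (random lists −0.37, percentile 0) and 0.65 ± 0.15 (random lists 0.21, percentile 100). A position between both groups is not particular to recurrence, because regressed superficial against primary nodular cells gave 0.39 ± 0.19 and −0.77 ± 0.30 for the same sets. Primary superficial against primary nodular cells gave 0.19 ± 0.05 and −0.42 ± 0.22. Single transcripts also lay outside: ENSDART00000009689 was at 56.8, 872 and 3495 CPM in primary, regressed and recurring nodular cells, and ENSDART00000164170 at 836, 29.5 and 949 CPM. Transcripts chosen in recurring against primary cells had 0.79 ± 0.07 (random lists −0.21) and −1.04 ± 0.16 (random lists −0.51) in regressed against primary nodular cells. Regressed superficial against the same primary nodular cells gave 0.77 ± 0.11 and −0.91 ± 0.13, and primary superficial cells 0.39 ± 0.50 and −0.78 ± 0.36, so these values do not set regressed nodular apart from regressed superficial cells. Within index set 1 the sets of regressed cells were 0.80 and −1.47 in recurring against primary cells, and within index set 2 the lower set was −0.60.

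Residual disease of the nodular and superficial subtypes was compared directly. Transcripts chosen as higher in regressed nodular cells had a held-out median of 0.83 ± 0.04 (random lists 0.22, percentile 100), and those chosen as lower −1.85 ± 0.32 (random lists −0.44, percentile 0). ENSDART00000022290 was at 1772 CPM (1725 to 1820) in regressed nodular and 60 CPM (51.8 to 69.2) in regressed superficial cells, a ratio of 29.5 (25.5 to 34.3). ENSDART00000009182 was at 1079 CPM (1043 to 1117) against 41.9 (35.1 to 49.7), with reads in 57.4% (44.1 to 70%) and 6.35% (1.76 to 15.5%) of the cells. The 3 pools gave log2 ratios of 6.76, 3.45 and 6.40 for it. ENSDART00000188962 had 0 reads in regressed nodular cells and 143 CPM (131 to 157) in regressed superficial cells, at least 146-fold lower against 3 counts over the group; unthinned, 1.64% of the regressed nodular cells had a read. With deposited TPM and a pseudocount of 1 TPM its log2 ratio was −3.89. ENSDART00000144439 had 1 read against 129 CPM (117 to 142), a log2 ratio of −6.62. The groups also differed in quality measures, with medians of 1830 and 3282 transcripts and 3.44% and 1.64% spike-in reads.

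Cells of each group were nearest to their own group in the other pools. Within an index set the groups lay largely on different i5 indexes in every pool. Nearness to the own group can therefore hardly be told apart from i5 index in any group. Under alternatives, the share of the own group was repeated only for recurring nodular cells, and the recurring share of regressed nodular cells was not repeated. Of the neighbours of regressed nodular cells, 37.5% were regressed nodular (chance 18.3%), 31.8% recurring nodular (25.4%), 13.4% primary nodular (23.9%) and 9.34% regressed superficial (19.9%). Recurring nodular cells had 52.6% recurring neighbours (25%) and 11.7% regressed nodular ones (18.6%). Their share of primary nodular neighbours, 21.4% (23.8%), changed sides of chance with the random draw of the thinning and lay below chance within both index sets, at ratios of 0.476 and 0.586. The share of primary nodular neighbours of regressed nodular cells, at a ratio of 0.563, was nearer to chance in every alternative. It reached 0.966 in index set 2 and exceeded chance, at 1.08, among cells with at least 2000 transcripts. Primary nodular cells had 51.9% primary nodular (23.8%), 32.8% recurring (25.2%), 5.63% regressed nodular (18.5%) and 3.75% primary superficial neighbours (12.4%), a ratio of 0.301 that was 0.16 among cells with at least 2000 transcripts. Their share of recurring neighbours was 19.3%, 30% and 41.2% in pools 1 to 3, so its excess over chance did not exceed its spread. Superficial cells had 48.8% (12.3%) and 52.2% (19.3%) neighbours of their own group for primary and regressed cells, and regressed superficial cells had 8.25% primary superficial ones (12.8%). The last share was 16.7%, 5.24% and 2.86% in pools 1 to 3, a spread larger than its distance from chance. No index set held both superficial groups, so index set and group cannot be told apart in how near they lay to each other.

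**Figure D3:**
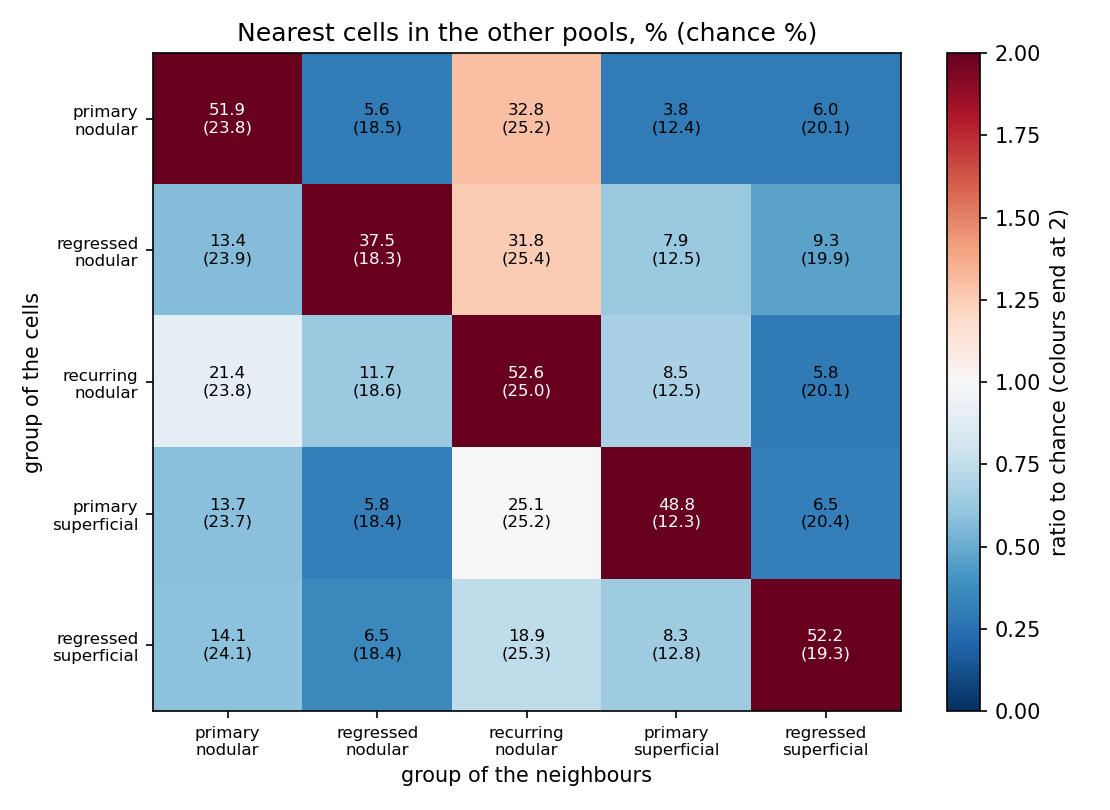
Percent of the 10 nearest cells in the other pools (columns, group of the neighbours) for the cells of each group (lines of the grid), with the percent given by the composition of those pools in brackets and the ratio of both as colour, where colours end at 2. Every group has its highest ratio to chance for neighbours of its own group, from 2.05 in regressed nodular to 3.98 in primary superficial cells. Group and i5 index can hardly be told apart here.

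Scaling by total counts or by the median of ratios shifted the groups against each other. The shift was 0.18 for regressed nodular, 0.14 for recurring nodular, −0.003 for primary nodular, −0.13 for regressed superficial and −0.18 for primary superficial cells on the log2 scale.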

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

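For the held-out sets, neighbours and per-cell values, all alternatives were chosen after the data were seen, although most had been listed for the gene lists; for the named transcripts, unthinned sums and means of per-cell CPM were set before the data were examined. Of 287 set values under other settings, 229 stayed within 1 SD over pools, 58 moved further and 0 changed sign; the cause was not tested except where the setting itself shows it. The planned use of every deposited cell added none at 50000 reads and was run at 20000 reads, which changes both choices. The planned removal of mitochondrial and ribosomal genes from the totals, removal of other cell types, removal of the cell contributing most, absence of a filter and everything on gene lists and mitfa were not run, because transcripts were not paired with genes or the list results did not exist. No replicate was left out, since each group is 1 sample. No paired analysis was possible because the results come from no test. Depth limits the per-cell values: at 50000 reads, 1 read is 20 CPM in a cell. Sets are named by comparison: subtype (primary nodular against superficial), nodular and superficial regression (regressed against primary), recurrence (recurring against regressed), return (recurring against primary nodular) and residual (regressed nodular against superficial).

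Unthinned sums gave −1.24 for lower nodular regression, 0.80 for higher recurrence, −1.15 for lower return and 0.89 for higher residual. Means of per-cell CPM gave −1.40 for lower return, −0.83 for lower nodular regression in recurring cells and 0.13 for higher nodular regression in superficial cells. Mean TPM gave 0.78 for higher nodular regression, 0.88 for higher recurrence, −1.33 for lower return, 0.65 for higher residual, −0.84 for lower nodular regression in recurring cells and 0.038 for higher nodular regression in superficial cells. A pseudocount of 10 gave −1.19 for lower return and −0.78 for lower nodular regression in recurring cells. Median-of-ratios scaling gave 1.13 for higher nodular regression, −1.14 for lower return, 1.14 for higher residual, −0.76 for lower nodular regression in recurring cells and 0.31 for higher superficial regression in nodular cells. A limit of 200 CPM gave 0.76 for higher nodular regression, 1.23 and −1.12 for superficial regression, −1.46 for lower residual, −0.78 for lower nodular regression in recurring cells and 0.11 for higher nodular regression in superficial cells. For lower return, every deposited cell and 20000 reads together gave −1.34, thinning to 20000 reads −1.33 and another random seed −1.33, and that seed gave −0.79 for lower nodular regression in recurring cells. Cells with at least 2000 transcripts gave 0.79 for higher nodular regression, −1.38 for lower return and 0.76 for higher residual. Index set 1 gave 1.11 and −2.05 for nodular regression, 1.41 and −2.25 for return, 0.92 and −2.31 for residual, and 0.80 and −1.47 for nodular regression in recurring cells. Index set 2 gave 1.06 for higher subtype, −1.05 for lower nodular regression, 0.88 for higher recurrence, 0.65 and −0.85 for return and −0.60 for lower nodular regression in recurring cells. Set means gave −1.99 for lower nodular regression, 2.32 for higher superficial regression, −1.35 for lower return, 0.93 for higher residual and 0.54 for higher nodular regression in superficial cells. Zeros set to 3 counts gave 0.23 for higher superficial regression in nodular cells. Leaving out the 10 libraries with many transcripts gave −0.83 for lower nodular regression in recurring cells, leaving out the 10 paired libraries of pool 2 gave 0.87 for higher residual, and leaving out all 20 gave −1.24 for lower return, 0.88 for higher residual and −0.83 for lower nodular regression in recurring cells.

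Of 174 other values, 140 stayed within 1 SD, 28 moved and 6 changed sides. The ratio to chance of primary nodular neighbours of recurring cells went from 0.900 to 1.06 with every deposited cell and 20000 reads, 1.099 at 20000 reads, 1.19 with another seed, 1.04 with 20 neighbours and 1.06 without the 20 libraries, and to 0.499 among cells with at least 2000 transcripts, 0.476 in index set 1 and 0.586 in index set 2. That of their regressed nodular neighbours went from 0.627 to 0.307 in index set 2. Of the named transcripts, unthinned sums moved ENSDART00000171722 (subtype) to 7.28, ENSDART00000009689 (return) to 5.37 and ENSDART00000145821 (return) to −2.05. Mean TPM with a pseudocount of 1 moved ENSDART00000171722 to 7.45, ENSDART00000009689 and ENSDART00000156574 (nodular regression) to 3.69 and −4.48, ENSDART00000185211 (superficial regression) to 5.22 and ENSDART00000188962 (residual) to −3.89. With mean TPM, ENSDART00000141338 (recurrence) went to 2.59, ENSDART00000111199 and ENSDART00000140957 (superficial regression) to −7.90 and −7.76. The ratio to chance of primary nodular neighbours of regressed nodular cells went from 0.563 to 1.08 among cells with at least 2000 transcripts and to between 0.668 and 0.966 in the other alternatives.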

Other observations

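The test of wells with several cells or bulk RNA and the test of index positions across pools were chosen only after the result was seen; the other tests below were written before theirs.

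The 10 libraries at 4 index pairs resembled their same-index partners in other pools, with correlations of 0.891 to 0.934, whereas the highest among the other same-index libraries was 0.736. Across different labelled groups, these 10 libraries also correlated with each other at a median of 0.830 (0.785 to 0.874). The likeness was therefore not limited to partners with the same index pair. The counts of these same-index partners differed by a median chi-square of 4.81 per degree of freedom, where 1 is sampling noise of reads. This argues against the same reads deposited again in each pool. A single library sequenced again in each pool cannot be judged this way. The division of shared reads by Salmon can add differences, and no known repeat of a library served as a reference. All 10 lay beyond the 95th percentile of transcripts and the 5th percentile of spike-in share of the other libraries, as wells with several cells or bulk RNA would. They were chosen by their correlation, which can be higher in libraries with many transcripts. Their transcript number is therefore not separate from the choice, whereas the spike-in share was not used in it. RNA of the labelled group stays open: 5 of the 10 correlated best with their own group, 3 recurring libraries correlated best with regressed superficial cells and 2 regressed nodular libraries with recurring cells. At each of the 4 index pairs the best group was the same in every pool that held it, so the 10 libraries are not independent answers. A biological explanation was not tested beyond this.

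In pool 2, the 5 same-i5 pairs of libraries from 2 i7 indexes had a median correlation of 0.840. Likeness of these index positions in any pool is argued against, since 4 such pairs in pools 1 and 3 had a median lower by 0.306. Of 519 combinations of i7 indexes compared within pools, this one had the largest excess of same-i5 correlation, at 0.273 (the next, 0.180). Part of the fall in the other pools can come from looking at the largest. Transcripts rare in pool 2 and present in 1 library of a pair were found in its partner a median of 12.7 times as often as in other cells of the group. Reads of one library in the other would give a high ratio. However, rarity was set on cells that include those compared and leave out the partner, which raises the ratio. No unpaired libraries were run to show the ratio without such reads. The ratio ranged from 2.61, in a regressed superficial pair from the second index to the first, to 23.3. From the first index to the second, 86.4 to 95.1% of these transcripts were found, and in reverse 20.1 to 71.8%. No biological explanation was tested.

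The higher set of regressed nodular cells may have come from the libraries that stood apart or from the index set. Without the 20 libraries the held-out median was 0.858, against 0.943 with all cells, which argues against them as the whole cause. Within index set 1 it was 1.108, which argues against the i7 index set as the whole cause there. Index set 2 gave no value for this set, so the planned reading in each index set was not complete. This split cannot judge the i5 index, because within index set 1 the 2 groups lay largely on different i5 indexes. The i5 index, the lower RNA content that the higher spike-in share of these cells would give, and animals, which no label names, stay open and untested. That residual nodular cells differ from primary cells in these transcripts remains a hypothesis from the same data.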
